A study of Oryza sativa with 12 samples.

How the data were processed

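Root RNA of rice inoculated with Rhizophagus irregularis was sequenced in 12 libraries, 3 from each of 4 groups (Azygous and idd7, each at 5 and 7 wpi), as given by the sample titles. Per the labels' protocols, RNA was extracted from 100 mg of root with TRIzol and libraries were made with the KAPA mRNA HyperPrep kit. The mutation type of idd7, whether replicates are separate plants, the annotation release and the strand setting of the counting are not given in the sources used here. The counts of genes that overlap a neighbour or an antisense transcript, or that share reads with a near-identical copy (NRT2.1 and NRT2.2, or the PR10 genes), are therefore uncertain.

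The deposited counts are raw read counts per gene from the authors, and the submitters' processing notes name FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 2.0.0, DESeq2 1.26.0 and the IRGSP-1.0 build. The deposited TPM values are from the authors too, and they equal the counts divided by 1 fixed length per gene and scaled (largest relative deviation 1.22e-14 over the 24578 genes with counts in all libraries). The count table holds 38866 features, 31942 of them with a count. Descriptions came from the deposited table, where 38798 features have a description and 16290 a symbol, only 6 of which are not locus numbers. The names of list members, such as PT11, were recalled from general knowledge of rice genes and checked only against these descriptions, so single names are uncertain. A reference gene table of assembly ASM3414082v1, another build, was used only to match identifiers, and 15918 of 16290 Entrez identifiers matched it. No values outside the 12 libraries were found.

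Counts were fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with TMM scaling, filterByExpr and 1 coefficient per group over all 12 libraries, which leaves 8 residual degrees of freedom. The filter kept 23878 genes and removed 14988, and the common biological coefficient of variation was 13.6%. The 5 contrasts were idd7 minus Azygous at each time, 7 minus 5 wpi in each genotype, and the interaction (the effect of idd7 at 7 wpi minus that at 5 wpi). P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with a threshold of 0.05. Totals from 13.6 to 19.8 M counts set the precision. Folds against a group with 0 counts were computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact Poisson 95% interval.

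The comparisons, the tests, the alternatives, 35 gene lists and the rule for named genes were chosen before the data were examined. Of the lists, 17 hold named genes (mycorrhiza markers, common symbiosis signalling, strigolactone, phosphate starvation, PHT1 transporters, nitrogen, gibberellin, defence, diterpenoid phytoalexins, the IDD family without IDD7, ground tissue, secondary wall, root hair, green tissue, dividing cells, heat and low oxygen, clock). The other 18 are families taken by a word in the description (GRAS, subtilisin, LysM, cytochrome P450, class III peroxidase, chitinase, ABC transporter, nitrate and peptide transporter, WRKY, ethylene response factor, lipid transfer, blue copper, expansin, germin, aquaporin, ribosomal, histone, glutathione transferase). These words also take in germination genes (germin list), a glutathione reductase (GRAS), glycolipid transfer proteins (lipid transfer), oligopeptide transporters (transporter) and histone-modifying enzymes (histone). AM3 and CERK1 are also in the LysM list, AM1 by its description in the peroxidase list, and SLR1 in the symbiosis and gibberellin lists. The description contradicted the name of 4 members (AM14, STR2, NADH-GOGAT1 and CASP1), which were dropped. The lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation of 0.01 between genes, adjusted over the 35 lists of a contrast, where at least 4 members were tested.

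Named genes were chosen by a rule. Among genes past the threshold, with a mean of at least 5 CPM in the higher group, all 3 libraries of one group above all 3 of the other and an informative symbol or description, the 12 largest rises and falls of each genotype contrast and the 8 largest of each time contrast were taken. Chance alone gives such a separation in 10% of genes for 3 against 3 libraries. From the interaction, up to 6 genes each way with the smallest adjusted p were taken. IDD7 and any list member could be named besides.

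The alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, limma-trend on log2(TPM + 1), replicate numbers as a block, a fit of only the 2 groups compared, leaving out each library in turn, camera with an estimated correlation, and fry. Counts thinned to the smallest total, a block within the 7 wpi libraries, a list of genes described as mycorrhiza-specific and a scan of shared descriptions were added after the data were seen. Whether replicate numbers pair libraries was checked by correlating deviations from the group means. At 7 wpi, same-numbered Azygous and idd7 libraries correlated at 0.204, 0.137 and 0.109 and other numbers at 0.069 or less. Values with a block, over all or only the 7 wpi libraries, are thus given where they end a call there.

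The procedure was tested on simulated counts drawn from the real means, with 200 genes changed. In the contrast at 5 wpi (23553 genes), 90.9% of 4-fold, 59.1% of 2-fold and 30.3% of 1.5-fold changes were recovered, with 7 false calls. At 7 wpi (23538 genes) the shares were 93.8%, 59.7% and 30.3%, with 5 false calls. Over time they were 92.4%, 65.2% and 21.5% in Azygous (23544 genes, 6 false calls) and 92.4%, 62.1% and 31.8% in idd7 (23563 genes, 8 false calls). For the interaction (23535 genes) they were 76.9%, 38.8% and 1.49%, with 7 false calls, so small interactions were mostly not detectable. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. No uninoculated roots and no measure of colonisation were among the values used here.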

Results

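RNA sequencing measured gene expression in roots of rice (cultivar Dongjin) inoculated with the arbuscular mycorrhizal fungus Rhizophagus irregularis and grown with 25 µM phosphate. The fungus supplies phosphate and nitrogen to root cortex cells through branched structures called arbuscules. Plants were of 2 genotypes, the idd7 mutant and Azygous, a term used for sister lines that did not inherit the insertion or transgene. IDD7 belongs to the indeterminate domain family of C2H2 zinc-finger transcription factors. Roots were harvested at 5 and 7 weeks post inoculation (wpi), which gave 4 groups of 3 libraries, named below by genotype (A for Azygous, M for idd7), time and replicate, as A5r1. Total counts were 14.31, 14.04 and 14.71 M (mega, SI prefix) in Azygous at 5 wpi and 13.63, 15.98 and 15.50 M in Azygous at 7 wpi. In idd7 they were 18.94, 18.55 and 19.31 M at 5 wpi and 17.09, 17.53 and 19.81 M at 7 wpi. The idd7 libraries were thus larger, at 18.5 ± 1.05 M against 14.7 ± 0.895 M (mean ± SD, n = 6 each, exact two-sided permutation p = 0.00216). The first principal component, with 58.3% of the variance, parted all 6 idd7 from all 6 Azygous libraries. The second, with 17.2%, parted the 5 wpi from the 7 wpi libraries. Within idd7 at 7 wpi, replicate 2 stood apart most, and its most abundant gene was IPS1 (Os03g0146800), at 2.03% of its counts. Expression levels below are counts per M total counts (CPM), given as mean ± SD over 3 libraries. Changes are log2 fold changes with their standard errors (SE). A gene rose or fell where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p below 0.05. The p-values measure only the spread between these samples, since the labels do not say whether replicates are separate plants. Intervals and floors for genes at or near 0 counts cover counting error only.

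The level of the targeted gene was read first. IDD7 (Os02g0518500) stood at 53.6, 45.5 and 69.0 CPM in Azygous at 5 wpi and at 70.3, 78.7 and 60.2 CPM at 7 wpi. In idd7 it stood at 1.69, 1.62 and 2.50 CPM at 5 wpi and at 4.05, 1.86 and 1.19 CPM at 7 wpi. All 6 idd7 libraries therefore lay below all 6 Azygous libraries. The transcript fell by 4.85 (SE 0.308, adjusted p = 9.15e-08) at 5 wpi and fell by 4.90 (SE 0.305, adjusted p = 8.33e-08) at 7 wpi. Between 5 and 7 wpi its level did not pass the threshold in Azygous (adjusted p = 0.419) or in idd7 (adjusted p = 0.605). The interaction of genotype and time was −0.05 (adjusted p = 0.961).

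At 5 wpi, the earlier of the 2 times, idd7 was compared with Azygous. The mycorrhiza marker list had the lowest median of the lists called. The gibberellin, defence, phytoalexin and ribosomal protein lists were also called lower in idd7. The expansin, class III peroxidase, root hair and phosphate starvation lists were called higher. These calls are by camera, which sets a list against all other genes with a preset correlation, and 0 of the 14 held with estimated correlation. In all, 6404 of 23878 genes passed the threshold, 3148 higher and 3256 lower in idd7, and 954 and 1303 of these changed at least 2-fold. The total was 4227 without A5r3. Limma-trend on log2(TPM + 1) is another test, on length-scaled values (TPM) without the TMM factors, which were lower in idd7. It gave 35.7% of called genes as higher, against 49.2% here.

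Of 9 tested mycorrhiza markers, 8 were lower in idd7 at 5 wpi, both over all genes and adjusted over the list alone, and their median change was −6.27. By camera the list was lower (adjusted p = 2.03e-11, and 0.195 with estimated correlation). In all 62 list results called here and below, the adjusted p with estimated correlation was above 0.05 and was the highest of all alternatives run. PT11 (Os01g0657100), the phosphate transporter of the membrane around arbuscules, fell by 7.56 (SE 0.361, adjusted p = 9.76e-09), from 110 ± 20.9 to 0.573 ± 0.288 CPM. PT13 (Os04g0186800), its relative, fell by 3.41 (SE 0.239, adjusted p = 2.34e-07). RAM2 (Os03g0735900), which makes lipid precursors passed to the fungus, fell by 7.72 (SE 0.353, adjusted p = 6.42e-09), from 112 ± 11.1 to 0.52 ± 0.148 CPM. STR1 (Os09g0401100), a transporter needed for arbuscule branching, fell by 6.87 (SE 0.34, adjusted p = 1.23e-08). AM3 (Os01g0783000), a secreted LysM protein, fell by 9.29 (SE 0.458, adjusted p = 1.19e-08), and AM1 (Os04g0134800) fell by 6.27 (SE 0.459, adjusted p = 3.41e-07), or −7.11 without M5r3. NPF4.5 (Os01g0748950), a nitrate transporter of colonised cells, fell by 4.72 (SE 0.297, adjusted p = 8.26e-08), from 409 ± 82.5 to 15.6 ± 5.39 CPM. The ammonium transporter AMT3;1 (Os01g0870300) fell by only 1.17 (SE 0.148, adjusted p = 6.53e-05). HA1 (Os03g0689300), a proton pump, stayed under 1 CPM in all groups and did not pass the threshold (adjusted p = 0.723).

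**Figure D1:**
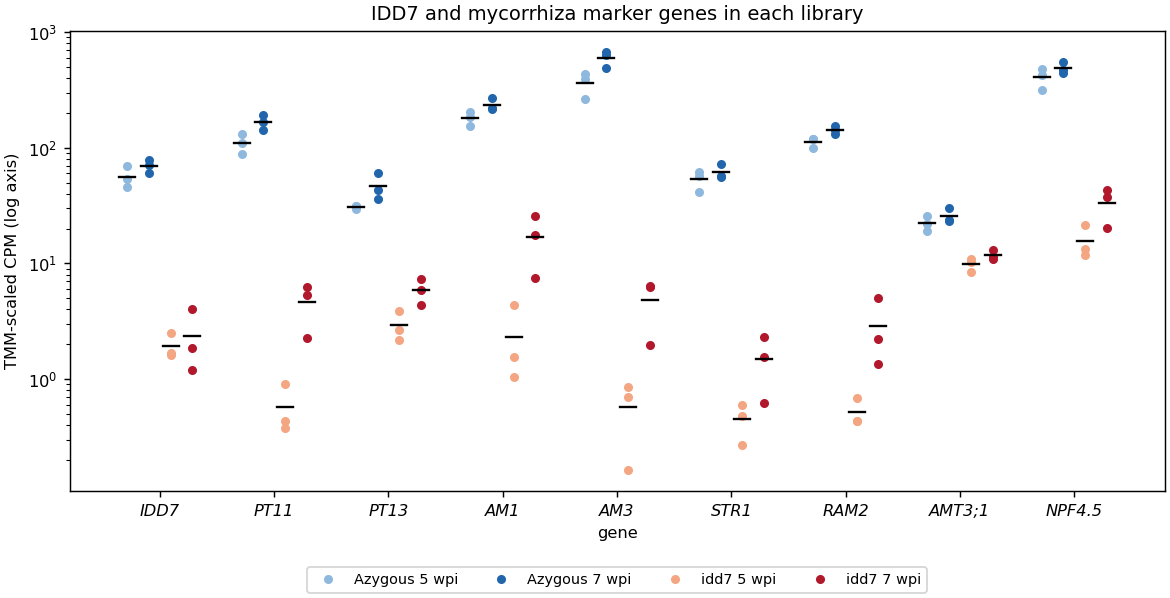
IDD7 and 8 mycorrhiza marker genes in each library, as TMM-scaled CPM on a log axis, for the 4 groups of genotype and time. Points are libraries and black lines are group means. PT11 has a mean of 110 CPM in Azygous and 0.573 CPM in idd7 at 5 wpi, and of 168 and 4.63 CPM at 7 wpi.

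The 12 largest falls at 5 wpi included 2 genes annotated as mycorrhiza-specific markers, beside proteases and other enzymes. Os05g0289700, annotated as mycorrhiza-specific marker 10 and resembling an acyltransferase, stood at 91.1 ± 37 CPM in Azygous and had 0 counts in the 3 idd7 libraries, at least 1680-fold lower over the group floor of 3 counts (adjusted p = 1.14e-07). A subtilisin-type protease (Os01g0868800) also had 0 counts in idd7 and was at least 707-fold lower (adjusted p = 7.47e-07). Cycloartenol synthase (Os11g0286400), an enzyme of sterol and triterpene synthesis, was at least 94.7-fold lower (adjusted p = 1.8e-05). For genes with 1 to 3 counts left in idd7, the ratio of Azygous to idd7 was 2160 for the cytochrome P450 Os01g0627800 (Poisson 95% interval 598 to 17800), 1300 for a kinase (Os12g0606000, 233 to 51200) and 526 for mycorrhiza-specific marker 25 (Os06g0552700, 180 to 2550). The same ratio was 638 for a cysteine proteinase (Os06g0582600, 177 to 5270), 593 for a glutathione transferase (Os10g0530300, 164 to 4900) and 571 for an aspartic protease (Os06g0306500, 158 to 4710). Another aspartic protease (Os06g0305400) fell by 8.94 (SE 0.304, adjusted p = 7.33e-10). Os01g0800600, described as 5a2 protein, fell by 10.38 (SE 0.52, adjusted p = 1.24e-08), or −11.59 without M5r1.

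The list of common symbiosis signalling genes, which act upstream of colonisation, had 1 higher, 5 lower and 6 not past the threshold, of 12 (the same counts adjusted over the list alone), and camera called it lower (adjusted p = 0.0307, 0.0692 without A5r2, and 0.348 with estimated correlation). NSP2 (Os03g0263300), a GRAS transcription factor of symbiosis signalling, fell by 1.94 (SE 0.15, adjusted p = 5.86e-07), and CYCLOPS (Os06g0115600), the target of the calcium-dependent symbiosis kinase, fell by 1.08 (SE 0.124, adjusted p = 2.76e-05). SMAX1 (Os08g0250900), a repressor of karrikin signalling, fell by 1.12 (SE 0.102, adjusted p = 2.99e-06), while D3 (Os06g0154200), the F-box protein that removes it, rose by 0.65 (SE 0.143, adjusted p = 0.00456). The family defined by GRAS descriptions had 6 higher, 15 lower and 26 not past of 47 (7 higher and 16 lower adjusted over the list alone) and was called lower (camera adjusted p = 0.0166, 0.348 with estimated correlation).

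The IDD family without IDD7 itself had 0 higher, 7 lower and 5 not past of 12 at 5 wpi (1 higher and 7 lower adjusted over the list alone), and camera called it lower (adjusted p = 0.00228, 0.208 with estimated correlation). IDD11 (Os01g0935000) fell by 4.04 (SE 0.324, adjusted p = 8.39e-07), or −4.80 without M5r3, IDD3 (Os09g0449400) fell by 2.33 (SE 0.269, adjusted p = 2.71e-05), and LPA1 (Os03g0237250), which sets shoot angle, fell by 1.33 (SE 0.2, adjusted p = 0.000282). SHR2 (Os03g0433200), of the SHORT-ROOT type that patterns root ground tissue and partners IDD proteins in other plants, fell by 1.64 (SE 0.175, adjusted p = 1.29e-05).

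The gibberellin list had 0 higher, 7 lower and 3 not past of 10 at 5 wpi (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 2.81e-05, 0.232 with estimated correlation). KAO (Os06g0110000), which makes the first gibberellin of the pathway, fell by 1.43 (SE 0.0892, adjusted p = 7.68e-08), GA20OX2 (Os01g0883800) fell by 2.00 (SE 0.172, adjusted p = 1.64e-06) and GA3OX2 (Os01g0177400), which makes the active form, fell by 1.38 (SE 0.139, adjusted p = 7.56e-06). The defence list had 0 higher, 7 lower and 8 not past of 15 (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.000163, 0.348 with estimated correlation). Without M5r3, 11 members were lower. PR1A (Os07g0129200), a marker of salicylate responses, fell by 1.78 (SE 0.243, adjusted p = 0.000124), and WRKY76 (Os09g0417600), a transcription factor of pathogen responses, fell by 2.26 (SE 0.274, adjusted p = 4.37e-05). The list of diterpenoid phytoalexin genes, whose products are antimicrobial, had 0 higher, 4 lower and 6 not past of 10 (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00103, 0.348 with estimated correlation). Without M5r1, 8 were lower. CYP99A3 (Os04g0178400), of momilactone synthesis, fell from 79.6 ± 2.27 to 17.3 ± 4.49 CPM (adjusted p = 0.000195), and MAS (Os04g0179200), the momilactone A synthase, fell by 2.55 (SE 0.485, adjusted p = 0.00167), or −3.62 without M5r1.

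Ribosomal protein genes made up the largest group of lower genes at 5 wpi, with 1 higher, 162 lower and 131 not past of 294 (1 higher and 189 lower adjusted over the list alone). Their median change was small, at −0.37 (camera adjusted p = 1.4e-18, 0.348 with estimated correlation). Without A5r3, 105 were lower. Of the 4 most abundant family members, chosen after their values were seen, 60S L2 (Os12g0567700) fell by 0.64 (SE 0.0874, adjusted p = 0.000124) and 40S S8 (Os04g0349500) fell by 0.58 (SE 0.0882, adjusted p = 0.000297). The cytochrome P450 family went both ways, with 19 higher, 42 lower and 88 not past of 149 (25 higher and 49 lower adjusted over the list alone). Camera called this family lower (adjusted p = 0.0195, 0.0692 without A5r2, and 0.348 with estimated correlation). Without A5r3, 12 members were higher. At 7 wpi it had 40 higher, 52 lower and 57 not past and was not called (camera adjusted p = 0.0805).

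Among the groups higher in idd7 at 5 wpi, the expansins, which loosen cell walls, had 21 higher, 1 lower and 12 not past of 34 (25 higher and 1 lower adjusted over the list alone; median 1.07; camera adjusted p = 5.23e-07, 0.348 with estimated correlation). The 2 most abundant, chosen after their values were seen, were Os10g0555700, which rose by 1.56 (SE 0.156, adjusted p = 7e-06), and Os03g0102700, which rose by 1.63 (SE 0.185, adjusted p = 2.29e-05). Class III peroxidases, which act on wall polymers, had 15 higher, 1 lower and 15 not past of 31 (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00103, 0.436 with estimated correlation). All 4 tested root hair genes were higher (also adjusted over the list alone; camera adjusted p = 0.0133, 0.348 with estimated correlation). The list's RTH1 (Os01g0899700) rose by 0.58 (SE 0.131, adjusted p = 0.00544). Its description, a protein with a pollen Ole e 1 allergen and extensin domain, does not bear out that name. Its place in the root hair list is therefore uncertain, here and below. CSLD1 (Os10g0578200), a wall synthase of root hairs, rose by 0.80 (SE 0.17, adjusted p = 0.00335). The heat and low-oxygen list had 2 higher, 0 lower and 3 not past of 5 (the same adjusted over the list alone; camera adjusted p = 0.0192, 0.348 with estimated correlation), and the alcohol dehydrogenase ADH2 (Os11g0210500) rose by 1.24 (SE 0.179, adjusted p = 2e-04). Some of these counts leaned on single libraries. Without A5r3, 12 expansins, 8 peroxidases and 2 root hair genes were higher, and without M5r3, 12 expansins and 9 peroxidases.

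The phosphate starvation list had 6 higher, 0 lower and 11 not past of 17 at 5 wpi (the same adjusted over the list alone; median 0.22; camera adjusted p = 0.019, 0.348 with estimated correlation). That list's adjusted p was 0.105 without A5r3, with 1 member higher, and 0.0542 without M5r3, also with 1. The count was 2 without A5r1 and 3 without M5r1. Among PHT1 phosphate transporters of the direct uptake pathway, PT2 (Os03g0150800) rose by 0.97 (SE 0.211, adjusted p = 0.00405) in 3 of 3 libraries. The PHT1 list was not called (1 higher, 1 lower and 6 not past of 8; camera adjusted p = 0.935), and its median was below 0 while its mean was above 0.

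The 12 largest rises at 5 wpi were led by non-symbiotic hemoglobin 2 (Os03g0226200), an oxygen and nitric oxide binding protein, which rose by 5.56 (SE 0.583, adjusted p = 1.11e-05), from 1.8 ± 0.538 to 84.9 ± 49.4 CPM. An acid phosphatase (Os01g0191200), of a type that releases phosphate from organic compounds, rose by 3.87 (SE 0.468, adjusted p = 4.26e-05), from 12 ± 6.74 to 174 ± 57.1 CPM. A peptide transporter of the PTR2 type (Os01g0871600) rose by 3.69 (SE 0.416, adjusted p = 2.18e-05), and a galactose oxidase-like protein (Os03g0258900) by 3.51 (SE 0.432, adjusted p = 4.94e-05). A terpenoid synthase (Os02g0571300), a Rieske protein (Os10g0567400) and a bHLH transcription factor (Os12g0111400) rose by 3.34, 3.32 and 3.19. The other 5 rose by 3.27 to 4.19, sizes that moved by over 1.5 times without A5r2. They were a sugar transporter of the MtN3 type (Os01g0606000), 2 dirigent-type genes (Os10g0335000 and Os10g0334500) and 2 genes with names from defence. Of these, a PR1a-like gene (Os07g0129300) rose by 3.50 (SE 0.732, adjusted p = 0.00321), or 4.56 without that library, and a thionin-like peptide (Os07g0429700) by 3.39, or 4.02.

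At 7 wpi, the later time, the same comparison was made. The mycorrhiza, gibberellin, defence, phytoalexin and ribosomal protein lists were again called lower in idd7, and so was the nitrogen list. The expansin, class III peroxidase and phosphate starvation lists were again called higher, and the lipid transfer, blue copper, secondary wall and PHT1 lists were called higher, unlike at 5 wpi. Of 19 lists called, 0 held with estimated correlation. Here 10151 genes passed the threshold, 5381 higher and 4770 lower, with 2389 and 1487 at least 2-fold. By limma-trend on log2(TPM + 1) 32.9% of called genes were higher, against 53% here, and the median of all genes was −0.135 against 0.0214.

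The mycorrhiza list again had 8 of 9 genes lower (also adjusted over the list alone), with a median of −3.87 (camera adjusted p = 4.23e-08, 0.318 with estimated correlation). PT11 fell by 5.19 (SE 0.285, adjusted p = 2.94e-08), from 168 ± 24.6 to 4.63 ± 2.09 CPM. AM3 fell by 6.97 (SE 0.376, adjusted p = 2.66e-08), STR1 fell by 5.39 (SE 0.292, adjusted p = 2.66e-08), AM1 fell by 3.80 (SE 0.382, adjusted p = 5.41e-06) and NPF4.5 fell by 3.87 (SE 0.282, adjusted p = 3.1e-07). The fall of RAM2 was −5.65 (SE 0.289, adjusted p = 1.78e-08), or −6.33 without M7r1. PT13 and AMT3;1 changed by −2.99 and −1.12, and HA1 did not pass the threshold (adjusted p = 0.451). Among the 12 largest falls, the ripening-related protein Os10g0489301 and an acid phosphatase of class B (Os05g0190300) had 0 counts in idd7 and were at least 148-fold (adjusted p = 0.000194) and at least 113-fold lower (adjusted p = 2.76e-05). A protease inhibitor (Os08g0441300) kept 2 counts, with a ratio of Azygous to idd7 of 152 (95% interval 42.1 to 1260). A short-chain dehydrogenase (Os02g0640600) fell by 7.38 (SE 0.257, adjusted p = 1.8e-09), the aspartic protease Os06g0306500 fell by 7.14 (SE 0.269, adjusted p = 2.25e-09), and a blue copper protein (Os03g0791300) fell by 6.30 (SE 0.425, adjusted p = 1.56e-07). Single idd7 libraries set the size of 5 others, as for marker 10 (Os05g0289700), at −9.84, or −10.95 without M7r1.

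NSP2 fell by 1.98 (SE 0.147, adjusted p = 3.58e-07), CYCLOPS fell by 1.71 (SE 0.127, adjusted p = 3.58e-07) and SMAX1 fell by 1.35 (SE 0.102, adjusted p = 4.1e-07) at 7 wpi. The common symbiosis list had 2 higher, 4 lower and 6 not past of 12 (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0483, 0.379 with estimated correlation). That call ended with replicate numbers as a block (adjusted p = 0.0544, and 0.0751 in the 7 wpi libraries alone) and without A7r3 (0.103), M7r2 (0.0654) or M7r3 (0.0514). The GRAS family had 10 higher, 17 lower and 20 not past of 47 (the same adjusted over the list alone; camera adjusted p = 0.0278, 0.327 with estimated correlation), with 5 higher without A7r2 and 6 without M7r1. The IDD family had 0 higher, 7 lower and 5 not past of 12 (the same adjusted over the list alone; camera adjusted p = 0.0154, 0.318 with estimated correlation). IDD11 fell by 2.97 (SE 0.278, adjusted p = 2.93e-06) and SHR2 fell by 1.64 (SE 0.167, adjusted p = 6.22e-06).

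The phosphate starvation list had 11 higher, 2 lower and 4 not past of 17 at 7 wpi (the same adjusted over the list alone; median 0.80; camera adjusted p = 0.0202, 0.0588 without M7r3, and 0.365 with estimated correlation). IPS1 (Os03g0146800), a non-coding RNA that accumulates when phosphate is short, rose by 3.00 (SE 0.402, adjusted p = 6.3e-05), from 1964 ± 689 to 15740 ± 5690 CPM. SPX1 (Os06g0603600), a phosphate sensor, rose by 1.45 (SE 0.188, adjusted p = 5.04e-05), and PAP10A (Os01g0776600), a secreted acid phosphatase, by 1.27 (SE 0.182, adjusted p = 0.000106). SQD1 (Os05g0387200), which replaces phospholipids with sulfolipids, rose by 1.00 (SE 0.158, adjusted p = 0.000232). The 2 lower genes were PHR3 (Os02g0139000), a regulator of the response, at −0.74 (SE 0.169, adjusted p = 0.00319), and PHO2 (Os05g0557700), which limits phosphate uptake, at −0.47 (SE 0.114, adjusted p = 0.00466). The PHT1 list had 5 higher, 0 lower and 3 not past of 8 (the same adjusted over the list alone; camera adjusted p = 0.0351, 0.473 with estimated correlation). PT2 rose by 1.60 (SE 0.217, adjusted p = 6.98e-05) and PT6 (Os08g0564000) by 1.43 (SE 0.239, adjusted p = 0.000359).

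**Figure D2:**
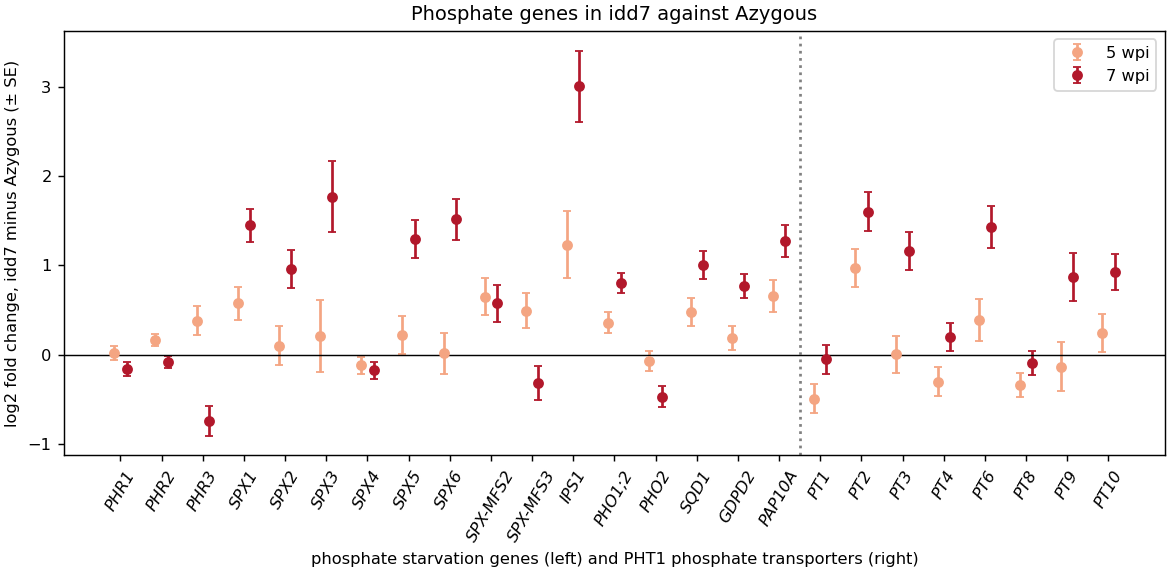
Log2 fold changes (idd7 minus Azygous) of 17 phosphate starvation genes, left of the dotted line, and of 8 PHT1 transporters, right of it, at 5 and 7 wpi, with bars of 1 standard error. At 7 wpi 11 of the 17 and 5 of the 8 passed the threshold as higher, and at 5 wpi 6 and 1. IPS1 changed by 1.23 at 5 wpi and 3.00 at 7 wpi.

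The nitrogen list was called lower at 7 wpi, with 1 higher, 7 lower and 5 not past of 13 (the same adjusted over the list alone; camera adjusted p = 0.00713, 0.318 with estimated correlation). The nitrate transporter NRT2.3 (Os01g0704100) fell by 2.15 (SE 0.206, adjusted p = 3.55e-06), and its partner protein NAR2.1 (Os02g0595900) fell by 1.22 (SE 0.229, adjusted p = 0.000876). NADH-GOGAT2 (Os05g0555600), of ammonium assimilation, fell by 2.03 (SE 0.236, adjusted p = 1.93e-05), while the nitrate reductase NIA1 (Os08g0468100) rose by 1.21 (SE 0.233, adjusted p = 0.00101). At 5 wpi the list was not called (2 higher, 2 lower and 9 not past; camera adjusted p = 0.495), although NRT2.3 fell by 1.39 (SE 0.201, adjusted p = 2e-04), NADH-GOGAT2 fell by 4.11 (SE 0.285, adjusted p = 2.11e-07), or −4.72 without M5r3, and NIA1 rose by 1.21 (SE 0.23, adjusted p = 0.00165). NRT2.2 (Os02g0112600), which shares reads with the near-identical NRT2.1 and is therefore uncertain, was at 25.6 ± 1.13 CPM in Azygous and 4.4 ± 0.967 CPM in idd7 at 7 wpi (adjusted p = 0.000161).

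The gibberellin list had 0 higher, 6 lower and 4 not past of 10 at 7 wpi (the same adjusted over the list alone; camera adjusted p = 0.0048, 0.318 with estimated correlation), and KAO fell by 1.29 (SE 0.0896, adjusted p = 1.96e-07). Defence genes had 0 higher, 9 lower and 6 not past of 15 (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.00116, 0.327 with estimated correlation). PBZ1 (Os12g0555500), a pathogen-induced PR10 protein with near-identical neighbours that leave its count uncertain, fell by 2.76 (SE 0.771, adjusted p = 0.0109), and WRKY76 fell by 1.95 (SE 0.272, adjusted p = 8.8e-05). Of the 10 phytoalexin genes 9 were lower (also adjusted over the list alone; median −2.83; camera adjusted p = 0.000149, 0.318 with estimated correlation). Their regulator DPF (Os01g0196300) fell by 2.16 (SE 0.235, adjusted p = 1.12e-05), CPS4 (Os04g0178300) fell by 2.88 (SE 0.424, adjusted p = 0.000134), and CYP99A3 fell by 2.78 (SE 0.325, adjusted p = 2.02e-05), or −3.40 without M7r1. Ribosomal protein genes had 9 higher, 166 lower and 119 not past of 294 (11 higher and 175 lower adjusted over the list alone; median −0.36; camera adjusted p = 3.89e-12, 0.318 with estimated correlation), and 40S S8 (Os04g0349500) fell by 1.09 (SE 0.0889, adjusted p = 8.85e-07). ABC transporters had 9 higher, 24 lower and 29 not past of 62 (the same adjusted over the list alone; camera adjusted p = 0.00732, 0.318 with estimated correlation). Of the most abundant ones, chosen after their values were seen, Os01g0356400 fell by 1.46 (SE 0.0936, adjusted p = 1.05e-07) and Os01g0724500 fell by 1.06 (SE 0.106, adjusted p = 5.57e-06). At 5 wpi the ABC list was not called (12 higher, 17 lower and 33 not past; camera adjusted p = 0.269), and its median changed sign with DESeq2 size factors.

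Expansins had 27 higher, 0 lower and 7 not past of 34 at 7 wpi (29 higher and 0 lower adjusted over the list alone; median 1.64; camera adjusted p = 6.37e-08, 0.318 with estimated correlation), and Os10g0555700 rose by 2.29 (SE 0.165, adjusted p = 2.85e-07). Class III peroxidases had 21 higher, 1 lower and 9 not past of 31 (23 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.57e-06, 0.318 with estimated correlation), and of the most abundant ones, chosen after their values were seen, Os05g0134400 rose from 114 ± 33.7 to 273 ± 18 CPM (adjusted p = 7.07e-05) and Os01g0294700 by 1.35 (SE 0.232, adjusted p = 0.000428). Lipid transfer proteins, which carry wall and cutin lipids, had 22 higher, 2 lower and 9 not past of 33 (23 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.67e-05, 0.318 with estimated correlation), and of 2 chosen by abundance Os05g0550300 rose by 1.05 (SE 0.14, adjusted p = 6.04e-05) and the glycolipid transfer protein Os02g0622400 fell by 0.63 (SE 0.086, adjusted p = 6.97e-05). Blue copper proteins had 23 higher, 3 lower and 14 not past of 40 (the same adjusted over the list alone; camera adjusted p = 0.000149, 0.318 with estimated correlation). The secondary wall list had 8 higher, 0 lower and 1 not past of 9 (the same adjusted over the list alone; camera adjusted p = 0.00116, 0.318 with estimated correlation). CESA4 (Os01g0750300), a cellulose synthase of xylem walls, rose by 1.36 (SE 0.242, adjusted p = 0.000562), and BC1 (Os03g0416200), needed for wall strength, by 1.47 (SE 0.243, adjusted p = 0.000323). At 5 wpi these last lists were not called, with 13 higher, 4 lower and 16 not past for lipid transfer, 14 higher, 5 lower and 21 not past for blue copper and 4 higher, 0 lower and 5 not past for secondary wall genes (camera adjusted p = 0.0517, 0.05 and 0.05). At 5 wpi the secondary wall genes higher by edgeR were 0 without A5r1 or A5r3, 1 without M5r3 and 2 without A5r2, M5r1 or M5r2. The blue copper genes higher were 7 without A5r3 or M5r3 and 9 without A5r1 or M5r2.

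All 5 heat and low-oxygen genes rose at 7 wpi (also adjusted over the list alone; camera adjusted p = 0.00207, 0.318 with estimated correlation), among them pyruvate decarboxylase PDC1 (Os05g0469600) by 3.26 (SE 0.399, adjusted p = 2.94e-05) and ADH2 by 1.49 (SE 0.18, adjusted p = 2.65e-05). Ethylene response factors had 8 higher, 0 lower and 16 not past of 24 (the same adjusted over the list alone; camera adjusted p = 0.0154, 0.0887 without M7r2, and 0.368 with estimated correlation). At 5 wpi they had 7 higher, 0 lower and 17 not past (camera adjusted p = 0.05). The root hair list had 3 higher, 0 lower and 1 not past of 4 at 7 wpi and was not called (camera adjusted p = 0.059). RTH1 rose by 1.69 (SE 0.138, adjusted p = 8.86e-07) and EXPA17 (Os06g0108600), a root hair expansin, by 2.31 (SE 0.399, adjusted p = 0.000458), while CSLD1 did not pass the threshold (adjusted p = 0.316).

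The 12 largest rises at 7 wpi included a ribonuclease of the S-like type (Os09g0537700) with 2 counts in Azygous, whose ratio of idd7 to Azygous was 2480 (95% interval 686 to 20500, adjusted p = 0.000162). The ribonuclease varied widely among idd7 libraries, at 100 ± 95.1 CPM. GH18 proteins of the chitinase and xylanase inhibitor fold rose by 6.28 (SE 0.496, adjusted p = 6.48e-07) (Os05g0247100, from 20.7 ± 8.55 to 1608 ± 148 CPM) and by 7.85, or 9.05 without A7r2 (Os05g0247800). Hemoglobin 2 (Os03g0226200) rose by 6.49 (SE 0.689, adjusted p = 8.92e-06), or 7.20 without A7r3. A thaumatin-like defence protein (Os12g0569300) rose by 5.67 (SE 0.541, adjusted p = 3.44e-06), and a multicopper oxidase tied to phosphate homeostasis (Os01g0127200) by 5.13 (SE 0.415, adjusted p = 8.07e-07), from 5.48 ± 1.94 to 193 ± 49.1 CPM. A lectin (Os04g0173800) rose by 4.10 (SE 0.335, adjusted p = 8.99e-07) and a phospholipid acyltransferase (Os10g0163370) by 4.70 (SE 0.336, adjusted p = 2.57e-07). The other 4 were dirigent-type, BURP and non-coding genes whose size moved by over 1.5 times without a single library, as for the dirigent-type gene Os10g0334500, at 5.73, or 7.56 without A7r1.

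With replicate numbers as a block in the 7 wpi libraries alone, 5 members of these and the strigolactone lists lost their calls. Over all 12 libraries the block ended the calls of Os01g0701400 (0.0526), CYP99A2 (0.0594) and SCR2 (0.0678). The 5 were CAD2 (Os02g0187800) of the secondary wall (adjusted p = 0.0628), GS1;1 (Os02g0735200) of nitrogen (0.0609), KO2 (Os06g0570100) of gibberellin (0.0512) and 2 MAX1-type genes of strigolactone synthesis (Os01g0701400, 0.0821, and Os06g0565100, 0.0779).

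Markers of other cells and states follow. Of 4 dividing-cell genes, 3 were higher at 5 wpi (by edgeR 0 without A5r3, M5r2 or M5r3 and 1 without A5r1 or A5r2) and 3 higher with 1 lower at 7 wpi (camera adjusted p = 0.228 and 0.188). KNOLLE (Os03g0736500), of cell plate formation, rose by 1.52 (SE 0.24, adjusted p = 0.000227) at 7 wpi, while PCNA (Os02g0805200), of DNA replication, fell by 0.46 (SE 0.127, adjusted p = 0.01). Histone genes had 0 higher, 3 lower and 3 not past of 6 at 5 wpi and 1 higher, 3 lower and 2 not past at 7 wpi (camera adjusted p = 0.102 and 0.198). Green tissue genes had 1 higher, 6 lower and 11 not past of 18 and then 6 higher, 3 lower and 9 not past (camera adjusted p = 0.12 and 0.654), with 3 lower at 5 wpi without M5r2, and their median at 7 wpi changed sign on log2(TPM + 1). Clock genes had 1 higher, 1 lower and 5 not past of 7 and then 2 higher, 1 lower and 4 not past (camera adjusted p = 0.228 and 0.631). LHY (Os08g0157600), a morning clock gene, rose by 0.61 (SE 0.112, adjusted p = 0.00125) at 5 wpi, and PRR95 (Os09g0532400) rose by 0.72 (SE 0.111, adjusted p = 0.000195) at 7 wpi. Ground tissue genes had 0 higher, 2 lower and 5 not past of 7 and then 0 higher, 3 lower and 4 not past (camera adjusted p = 0.05 and 0.392).

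The remaining lists were called at neither time by camera. Strigolactone genes had 1 higher, 4 lower and 6 not past of 11 at 5 wpi and 5 higher, 4 lower and 2 not past at 7 wpi, where 2 were higher without A7r1, A7r3 or M7r3 and 3 without A7r2 or M7r2. Their synthesis gene D10 (Os01g0746400) fell by 1.23 (SE 0.119, adjusted p = 5.06e-06) at 5 wpi and D17 (Os04g0550600) fell by 1.05 (SE 0.114, adjusted p = 1.58e-05). Chitinases had 6 higher, 9 lower and 7 not past of 22 and then 10 higher, 9 lower and 3 not past. Of the most abundant ones, chosen after their values were seen, the acidic endochitinase Os01g0860400 fell by 3.28 (SE 0.234, adjusted p = 2.72e-07) at 5 wpi and fell by 2.74 (SE 0.226, adjusted p = 9.77e-07) at 7 wpi. Os10g0416500 rose by 1.23 (SE 0.259, adjusted p = 0.00338) and by 1.21 (SE 0.26, adjusted p = 0.00218). LysM genes had 1 higher, 5 lower and 10 not past of 16 and then 5 higher, 4 lower and 7 not past, and a LysM receptor kinase annotated with mycorrhiza (Os03g0233300, chosen in the same way) fell by 1.16 (SE 0.101, adjusted p = 1.95e-06) at 5 wpi and fell by 0.84 (SE 0.1, adjusted p = 2.43e-05) at 7 wpi. The LysM gene Os03g0133400 rose there by 0.88 (SE 0.155, adjusted p = 0.000504). Nitrate and peptide transporters had 5 higher, 11 lower and 12 not past of 28 and then 6 higher, 10 lower and 12 not past, and germin-like genes 10 higher, 15 lower and 16 not past of 41 and then 11 higher, 17 lower and 13 not past. Glutathione transferases had 14 higher, 6 lower and 25 not past of 45 and then 17 higher, 8 lower and 20 not past, with 5 lower at 7 wpi without A7r2 or M7r1. Subtilisins had 7 higher, 4 lower and 24 not past of 35, with 4 higher without A5r3 or M5r1, and then 9 higher, 7 lower and 19 not past. WRKY genes had 7 higher, 13 lower and 56 not past of 76 and then 11 higher, 16 lower and 49 not past, with 7 higher at 7 wpi without A7r1 or A7r3. Aquaporins had 4 higher, 2 lower and 4 not past of 10 and then 5 higher, 1 lower and 4 not past. The medians of the LysM list at both times and of the WRKY, subtilisin and ground tissue lists at 7 wpi changed sign on log2(TPM + 1), where that of the WRKY list at 5 wpi was 0. The median of the glutathione transferase list at 5 wpi changed sign with DESeq2 size factors. Median, mean and camera direction differed in sign for the LysM, WRKY, glutathione transferase and subtilisin lists at 5 wpi and for the LysM, WRKY, subtilisin, clock and ground tissue lists at 7 wpi.

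**Figure D3:**
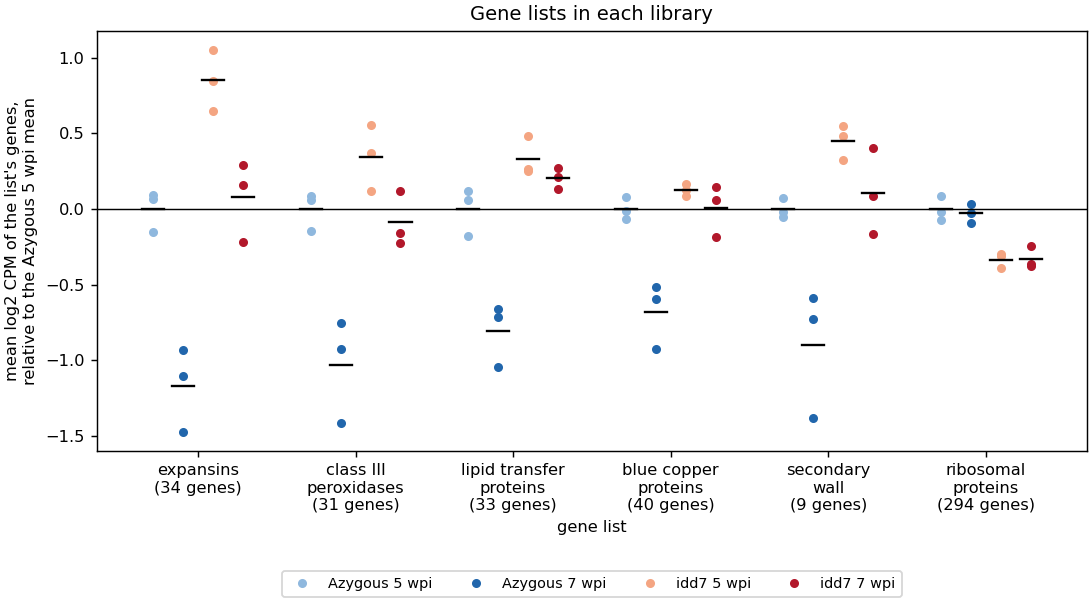
Mean log2 CPM of the genes of 6 lists in each library, relative to the mean of Azygous at 5 wpi, with points for libraries and lines for group means. Expansins (34 genes), class III peroxidases (31), lipid transfer proteins (33), blue copper proteins (40) and secondary wall genes (9) lie higher in idd7 than in Azygous at 7 wpi, and ribosomal protein genes (294) lie lower in idd7 at both times. These genotype directions held with DESeq2 size factors, on log2(TPM + 1) and in thinned counts.

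The effects of idd7 at the 2 times came from separate libraries and overlapped widely. Genes higher at both times numbered 2299, where lists drawn independently would share 709.4, and genes lower at both times 2268, against 650.4. Only 73 genes passed the threshold in opposite directions. Across all tested genes, which are not independent replicates, the log2 changes at 5 and 7 wpi had a Pearson r of 0.80 and a covariance of 0.725. IDD7, PT11, AM3, KAO, IDD11 and the hemoglobin gene Os03g0226200 were among the genes with the same direction at both times.

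The interaction asked where the effect of idd7 at 7 wpi differed from that at 5 wpi. Camera called 11 lists (0 with estimated correlation), although few members of each passed singly. The mycorrhiza, lipid transfer, blue copper and chitinase lists had a higher effect at 7 wpi, and the nitrogen and ABC transporter lists a lower one. Of all genes, 1239 passed the threshold, 744 with a higher and 495 with a lower effect at 7 wpi, and 421 and 128 of these differed at least 2-fold. The higher share was 60%, against 48.9% with DESeq2 size factors and 48.3% by the DESeq2 test. This count was sensitive to single libraries, with 345 without A5r2, 1887 without M5r3 and 394 to 729 without A5r1, A7r1, A7r2, A7r3, M5r1, M5r2, M7r1 or M7r2. By point estimates, the effect was lower at 5 wpi and higher at 7 wpi in 288 genes and the reverse in 284, while 375 were higher and 169 lower at both times with a larger effect at 7 wpi. In 81 lower and 42 higher genes the effect was smaller at 7 wpi.

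Of the mycorrhiza list, 4 genes had a higher, that is less negative, effect at 7 wpi (5 adjusted over the list alone), with a camera adjusted p of 0.0134 (0.655 with estimated correlation). The interaction was 2.36 (SE 0.497, adjusted p = 0.0221) for PT11, 2.47 (SE 0.564, adjusted p = 0.0282) for AM1, 2.32 (SE 0.613, adjusted p = 0.0464) for AM3 and 2.07 (SE 0.51, adjusted p = 0.0363) for RAM2. With replicate numbers as a block, AM3 (0.0561) and RAM2 (0.0556) did not pass. By edgeR 0 of the 9 passed without A5r2, M5r1, M5r2 or M7r2, 1 without A5r1, A7r1 or A7r2 and 2 without A5r3, A7r3 or M7r1. Lipid transfer proteins had 8 higher, 1 lower and 24 not past of 33 (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.5e-05, 0.655 with estimated correlation), with 3 higher without A5r2 and 4 without A5r1. Blue copper proteins had 8 higher, 0 lower and 32 not past of 40 (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000104, 0.655 with estimated correlation). They had 2 higher without A5r2 or A7r2, 3 without A5r1 or M5r2, 4 without M5r1 or M7r2 and 5 without A7r1, A7r3 or M7r1. The blue copper gene Os02g0653200, chosen by abundance after its values were seen, had an interaction of 1.15 (SE 0.203, adjusted p = 0.013). Chitinases had 2 higher, 0 lower and 20 not past of 22 (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00113, 0.161 without M5r2, and 0.655 with estimated correlation). ABC transporters had 0 higher, 4 lower and 58 not past of 62 (the same adjusted over the list alone; camera adjusted p = 0.0143, 0.655 with estimated correlation), with 1 lower without M5r2 and 2 without A5r1 or A5r2. Nitrogen genes had 1 higher, 2 lower and 10 not past of 13 (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00624, 0.655 with estimated correlation).

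Peroxidases had 3 higher, 0 lower and 28 not past of 31 in the interaction (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00131, 0.655 with estimated correlation). By edgeR 0 were higher without A5r1, A5r2, M5r1, M5r2 or M7r1 and 1 without A7r2 or M7r2. AM1 is 1 of the 3 higher. PHT1 transporters had 1 higher, 0 lower and 7 not past of 8 (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00603, 0.655 with estimated correlation). The phosphate starvation list was not called (1 higher, 1 lower and 15 not past of 17; camera adjusted p = 0.288), so its effect is not shown to differ between the times, although SPX6 (Os07g0614700) passed singly (adjusted p = 0.0236). The lists of secondary wall genes, expansins and green tissue genes were also called (camera adjusted p = 0.0333, 0.0392 and 0.0398; 0.655, 0.718 and 0.655 with estimated correlation). With edgeR 0, 1 and 2 of their members passed (2 higher and 0 lower, 0 higher and 0 lower and 4 higher and 0 lower adjusted over the list alone). Single libraries ended each of these 3 calls, with the adjusted p of expansins at 0.238 without A7r3, of secondary wall genes at 0.152 without M7r1 and of green tissue genes at 0.0588 without M5r2.

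Single genes with the smallest adjusted p in the interaction included DAHP synthase (Os03g0389700), the entry to aromatic amino acid synthesis, at 1.16 (SE 0.147, adjusted p = 0.00858), and a phenylalanine ammonia-lyase (Os04g0518100), the entry to lignin and phenolics, at 1.03 (SE 0.147, adjusted p = 0.0089). The lyase fell from 284 ± 27.5 to 133 ± 8.21 CPM in Azygous and stood at 394 ± 18.6 and 379 ± 48.7 CPM in idd7. Os02g0668900 had an interaction of 1.87 (SE 0.229, adjusted p = 0.00858), an α/β hydrolase (Os01g0636400) 1.13, an aminoacyl-tRNA synthetase (Os06g0321700) 1.76 and an X8 domain protein (Os05g0581900) 1.43. Lower effects at 7 wpi were found for the transporter PDR3 (Os01g0609300), at −1.75 (SE 0.242, adjusted p = 0.0089), another transporter of this ABC type (Os11g0587600), at −0.81 (SE 0.11, adjusted p = 0.00875), and MDR1 (Os01g0533900), at −0.91 (SE 0.108, adjusted p = 0.00858). Os01g0689451, a kinesin (Os05g0117798) and a bZIP transcription factor (Os06g0662200) followed at −1.51, −0.97 and −1.10. RTH1 had a higher effect at 7 wpi (1.12 (SE 0.189, adjusted p = 0.0123)), as did PRR95 (0.99 (SE 0.157, adjusted p = 0.00978)), while LHY (−0.94 (SE 0.158, adjusted p = 0.0116)) and DPF (−1.72 (SE 0.313, adjusted p = 0.0137)) had lower ones.

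Over time in Azygous, from 5 to 7 wpi, the comparison followed roots with normal IDD7. The expansin, peroxidase, lipid transfer and dividing-cell lists were called lower (13 lists called in all, 0 with estimated correlation). In all 3329 genes passed the threshold, 1054 higher and 2275 lower at 7 wpi, with 137 and 1081 at least 2-fold. The total was 1692 without A5r1, 1879 without A7r2 and 1830 without A7r3.

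Expansins had 0 higher, 24 lower and 10 not past of 34 over time in Azygous (0 higher and 27 lower adjusted over the list alone; median −1.51; camera adjusted p = 2.51e-13, 0.235 with estimated correlation), with 14 lower without A7r3 and 15 without A5r1. The expansin Os10g0555700 fell by 1.36 (SE 0.165, adjusted p = 0.000548). Peroxidases had 0 higher, 19 lower and 12 not past of 31 (0 higher and 24 lower adjusted over the list alone; camera adjusted p = 5.23e-12, 0.235 with estimated correlation), and Os01g0294700 fell by 1.78 (SE 0.234, adjusted p = 0.000768). Lipid transfer proteins had 0 higher, 17 lower and 16 not past of 33 (0 higher and 21 lower adjusted over the list alone; camera adjusted p = 6.86e-10, 0.235 with estimated correlation). Blue copper proteins had 0 higher, 15 lower and 25 not past of 40 (1 higher and 19 lower adjusted over the list alone; camera adjusted p = 2.61e-07, 0.235 with estimated correlation). Secondary wall genes had 0 higher, 6 lower and 3 not past of 9 (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 3.33e-05, 0.278 with estimated correlation), with 3 lower without A5r2. All 4 dividing-cell genes fell (also adjusted over the list alone; camera adjusted p = 0.000836, 0.278 with estimated correlation), 2 of them without A5r1, A7r2 or A7r3. Root hair genes had 0 higher, 2 lower and 2 not past of 4 (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0114, 0.235 with estimated correlation).

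Germin-like genes had 1 higher, 9 lower and 31 not past of 41 over time in Azygous (2 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.000836, 0.543 with estimated correlation), with 4 lower without A7r2 or A7r3 and 5 without A5r1 or A7r1. Chitinases had 0 higher, 4 lower and 18 not past of 22 (the same adjusted over the list alone) and were called lower (camera adjusted p = 0.0143, 0.081 without A5r2, 0.0628 without A7r1, and 0.543 with estimated correlation). The mycorrhiza list was called higher with a median of 0.38 (camera adjusted p = 0.0256, 0.0728 without A5r1, 0.0903 without A7r3, and 0.543 with estimated correlation). By edgeR 0 of its 9 genes passed over all genes and 4 were higher adjusted over the list alone. PT11 and AM3 did not pass over all genes (0.61, adjusted p = 0.0889, and 0.72, adjusted p = 0.103), but passed by limma-voom and in a fit of these groups alone. The IDD, green tissue and GRAS lists were called higher (camera adjusted p = 0.0268, 0.0294 and 0.0348; 0.235, 0.543 and 0.543 with estimated correlation). Each of these 3 calls ended without A7r3 (0.0603, 0.0556 and 0.0603) and without at least 3 other single libraries.

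The largest falls in Azygous were those of chalcone synthase (Os07g0525500), of flavonoid synthesis, at −4.23 (SE 0.577, adjusted p = 0.00088), a GDSL lipase (Os05g0506600), at −2.71 (SE 0.308, adjusted p = 0.000398), a lipid transfer protein (Os07g0174900), at −2.64 (SE 0.28, adjusted p = 0.000262), the multicopper oxidase Os01g0127200, at −2.47 (SE 0.399, adjusted p = 0.00199), and a β-1,3-glucanase (Os01g0940800), at −2.47 (SE 0.541, adjusted p = 0.00942). A germin-like gene (Os04g0617900) fell by 3.83 (SE 0.952, adjusted p = 0.0176), a call that ended without A5r1, A7r1 or A7r2. Among the largest rises were a methyltransferase (Os11g0260100), at 1.97 (SE 0.238, adjusted p = 0.000539), a MYB transcription factor (Os02g0685200), at 1.69 (SE 0.154, adjusted p = 0.000201), and the MADS factor MADS15 (Os07g0108900), at 1.49 (SE 0.193, adjusted p = 0.000672).

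Over time in idd7, from 5 to 7 wpi, the comparison followed roots with little IDD7 transcript. The mycorrhiza, green tissue and PHT1 lists were called higher, and the expansin and peroxidase lists lower (0 of 5 with estimated correlation). In all 8658 genes passed the threshold, 4314 higher and 4344 lower at 7 wpi, with 1007 and 1101 at least 2-fold. By limma-trend on log2(TPM + 1) 35.8% of called genes were higher, against 49.8% here.

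Of the 9 mycorrhiza markers, 7 rose in idd7 between 5 and 7 wpi (also adjusted over the list alone; median 1.68; camera adjusted p = 0.000466, 0.668 with estimated correlation). PT11 rose by 2.97 (SE 0.427, adjusted p = 0.000301), AM3 by 3.04 (SE 0.525, adjusted p = 0.000925), AM1 by 2.85 (SE 0.45, adjusted p = 0.000533), or 3.69 without M5r3, and RAM2 by 2.42 (SE 0.452, adjusted p = 0.00148), or 1.74 without M7r1. NPF4.5 rose by 1.11 (SE 0.271, adjusted p = 0.00703) and PT13 by 1.00 (SE 0.255, adjusted p = 0.00863), while AMT3;1 did not pass the threshold (adjusted p = 0.217). Their levels at 7 wpi stayed below Azygous, with AM1 at 17 ± 9.11 against 235 ± 28.2 CPM and NPF4.5 at 33.6 ± 11.9 against 489 ± 54.3 CPM. Also higher were 2 germin-like genes (Os09g0568600, 2.85 (SE 0.398, adjusted p = 0.000258), and Os09g0568700, 2.84 (SE 0.386, adjusted p = 0.000218)). PHT1 transporters had 5 higher, 0 lower and 3 not past of 8 (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0279, 0.675 with estimated correlation), with 3 higher and an adjusted p of 0.115 without M5r2, 3 and 0.110 without M7r1, and 0.113 without M7r2.

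Green tissue genes had 10 higher, 0 lower and 8 not past of 18 in idd7 over time (11 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000572, 0.668 with estimated correlation). A chloroplast biogenesis factor (Os09g0458400) was at 8.74 ± 0.649 and 14.3 ± 1.55 CPM (adjusted p = 0.00143), and photosystem II protein Psb28 (Os01g0938100), also chosen by abundance after its values were seen, rose by 0.87 (SE 0.222, adjusted p = 0.00882). Expansins had 1 higher, 16 lower and 17 not past of 34 (1 higher and 20 lower adjusted over the list alone; camera adjusted p = 0.000155, 0.675 with estimated correlation), and Os10g0555700 fell by 0.63 (SE 0.151, adjusted p = 0.00622). Peroxidases had 1 higher, 13 lower and 17 not past of 31 (1 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.00762, 0.71 with estimated correlation). Their adjusted p was 0.0767 without M5r3, and 6 were lower without that library or M7r2 or M7r3, and 8 without M5r1. All 4 dividing-cell genes fell here too, without a list call (camera adjusted p = 0.0537), and 1 fell without M5r2 or M7r2 and 2 without M7r3.

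Among the largest changes in idd7 over time, the GH18 gene Os05g0247800 rose by 4.20 (SE 0.334, adjusted p = 2.01e-05) and the heat stress factor HSF29 (Os01g0733200) by 2.95 (SE 0.298, adjusted p = 4.68e-05). The S-like ribonuclease Os09g0537700 rose by 3.39 (SE 0.843, adjusted p = 0.0077), or 4.96 without M5r1 and 2.25 without M7r3, and did not pass by DESeq2. A germin-like gene (Os08g0231400) fell by 3.62 (SE 0.442, adjusted p = 0.000119), a sulfate transporter (Os03g0196000) fell by 2.43 (SE 0.252, adjusted p = 4.87e-05), a disease resistance protein (Os12g0237900) fell by 2.56 (SE 0.426, adjusted p = 0.000733) and the peptide transporter Os01g0871600 fell by 2.42 (SE 0.365, adjusted p = 0.000392).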

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

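Of the tests in this part, thinning to the smallest total, the one on carried-over reads and the sorting of the splits by their make-up were chosen only after the result was seen. Each value below is the interaction, the log2 effect of idd7 at 7 wpi minus that at 5 wpi, listed because its test passed the threshold.

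Genes with the smallest adjusted p by edgeR were Os02g0668900 (1.87), Os03g0389700 (1.16), Os01g0636400 (1.13), Os06g0321700 (1.76), Os04g0518100 (1.03) and Os05g0581900 (1.43) with a higher effect at 7 wpi. With a lower effect they were Os01g0533900 (−0.91), Os01g0689451 (−1.51), Os11g0587600 (−0.81), Os01g0609300 (−1.75), Os05g0117798 (−0.97) and Os06g0662200 (−1.10). Mycorrhiza genes were PT11 (2.36), AM1 (2.47), AM3 (2.32) and RAM2 (2.07). Strigolactone and phosphate genes were the MAX1-type gene Os01g0700900 (0.79), PHR3 (−1.12), SPX6 (1.5) and PT3 (1.15). Nitrogen genes were NRT2.2 (−2.07, or −1.32 without idd7 5 wpi replicate 2), GS1;2 (−0.71) and NADH-GOGAT2 (2.08). CPS1 of gibberellin synthesis had 0.52, the defence gene JIOSPR10 0.82 and the phytoalexin regulator DPF −1.72. Members of the root hair list were CSLD1 (−1.03) and RTH1 (1.12, a name that is uncertain), and clock genes LHY (−0.94), PRR95 (0.99) and GI (0.71). Each of CPS1, AM3, RAM2, AM1, CSLD1, PT11, GI, Os01g0700900, PT3, GS1;2, NRT2.2, SPX6, PHR3, JIOSPR10 and NADH-GOGAT2 lost its call in at least 1 alternative.

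Lists called by camera were mycorrhiza markers (median 1.47), PHT1 transporters (0.66), nitrogen (−0.55), secondary wall (0.50), green tissue (0.53), peroxidases (0.62), chitinases (0.80), ABC transporters (−0.16), lipid transfer (0.78), blue copper (0.61) and expansins (0.60). On log2(TPM + 1) each median kept its sign but was 0.654 for mycorrhiza, 0.215 for green tissue, 0.348 for peroxidase and 0.188 for expansin genes. There 0 mycorrhiza, PHT1, secondary wall, peroxidase and expansin genes passed by limma-trend (4, 1, 0, 3 and 1 by edgeR). With an estimated correlation 0 of these 11 were called (11 by the preset correlation, 0 by fry). Of 100 drawn splits of the 12 libraries, 8, the real one included, called as many genes as the real interaction, so this count did not exclude chance. The real split called 1239 genes and the highest other 9353. All 7 larger splits kept the idd7 libraries of 1 time together, a property of 14 drawn splits. They carry the change of idd7 over time (8658 genes) into the contrast and point to that structure of the samples, so they are no measure of chance. The highest among splits that mixed the times of both genotypes called 13.

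The first pattern was that mycorrhiza markers in idd7 stood higher at 7 than at 5 wpi. Reads carried over from Azygous libraries would give every marker the same fraction of its Azygous level, but of 15 marker genes 14 of 14 others exceeded, by their lower Poisson bound, the upper bound (0.194%) of the lowest marker, Os05g0289700, at 0.105% (AM3 0.776%, PT11 2.69%, AM1 7.00%, PT13 12.4%). A single mixed or mislabelled library would raise 1 library, but in 3 of 3 idd7 libraries at 7 wpi the summed marker level (101, 82.3 and 39.8 CPM) lay above that of every idd7 library at 5 wpi (19.1, 19.2 and 31.9 CPM). Later colonisation may underlie the rise, but it and fungal RNA were not tested. Overlapping IDD7 levels in idd7 (1.62 to 2.50 and 1.19 to 4.05 CPM at 5 and 7 wpi) argue against its direct effect.

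The second pattern was the higher phosphate starvation list in idd7 at 7 wpi. The idd7 replicate that stands apart, replicate 2, was not its cause alone, since 11 of 11 higher members kept their call without that library. Larger idd7 libraries were not its cause alone either, since 11 of 11 kept it after thinning to the smallest total, although without idd7 replicate 3 the list's own adjusted p was 0.0588 (0.00147 to 0.365 over the alternatives). A lower phosphate supply by the fungus may underlie the rise, and a direct effect of IDD7 on these genes stays open, as neither was tested.

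The third pattern was that 35 of 68 expansin, peroxidase and root hair genes were called higher in idd7 at both times, although the root hair list itself was not called at 7 wpi. Larger libraries alone did not account for it, as 32 of the 35 genes kept both calls after thinning. More dividing root tip tissue would raise DNA replication and mitosis genes too, but in 3 of 4 cases (2 sets at 2 times) the median was at or below 0 without a call as higher, with DNA replication medians of −0.10 and −0.14 (0 higher and 4 lower, then 1 and 5, of 31) and mitosis medians of −0.08 and 0.04 (4 higher and 2 lower, then 5 and 4, of 19) at 5 and 7 wpi. The pattern's own medians were 0.783 and 1.42 (camera adjusted p 0.183 and 0.133 for DNA replication, 0.944 and 0.913 for mitosis). On the other side, the planned list of 4 dividing-cell genes had medians of 0.70 and 1.23, near those of the pattern, with CYCB1;1, CDKB2;1 and KNOLLE higher at both times. Some set members had been seen before, so dividing tissue may still have a part, and a larger share of young, non-dividing tissue was not tested.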

How the results depend on the processing

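Thinned counts, the block within 7 wpi, the list of described mycorrhiza genes and the description scan were tests chosen only after the results were seen; all other alternatives were planned. Of 441 gene results, 318 kept direction and side of the threshold in every alternative run, and 120 lost the threshold in at least 1 (1 of them reversed in another). The other 3, not past it at first, passed in at least 1 (PT11 and AM3 over time in Azygous and NPF4.5 in the interaction). Losses numbered 418 of 2850 when leaving out 1 library, 53 of 441 on log2(TPM + 1), 20 of 441 by limma-voom, 9 of 438 by DESeq2, 19 of 402 with only the 2 groups, 6 of 441 without a filter, 4 of 441 with DESeq2 size factors and 6 of 440 after thinning. They numbered 20 of 441 with replicate numbers as a block and 5 of 142 with a block within 7 wpi. All 62 list calls were lost with an estimated correlation, 18 by fry, 2 after thinning, 2 with replicate numbers as a block (green tissue in the interaction, adjusted p 0.0503, and common symbiosis at 7 wpi, 0.0544) and 0 with DESeq2 size factors. IDD7 changed by −5.07 to −4.67 at 5 wpi and by −5.53 to −4.55 at 7 wpi when 1 library was left out. Fewer libraries lower the degrees of freedom, and the pseudocount of log2(TPM + 1) shrinks folds of low genes, while the causes of other losses were not tested.

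Genes past the threshold ranged from 4227 (without Azygous replicate 3) to 5406 at 5 wpi, from 8161 to 9408 at 7 wpi and from 6275 to 7736 over time in idd7 when 1 library was left out. Over time in Azygous they ranged from 1692 (without 5 wpi replicate 1) to 2752, with 1879 and 1830 without 7 wpi replicates 2 and 3. For the interaction they ranged from 345 (without Azygous 5 wpi replicate 2) to 1887 (without idd7 5 wpi replicate 3). The count was 2179 by DESeq2 and 821 on log2(TPM + 1), against 1239, and the cause was not tested. At 5 wpi DESeq2 size factors gave 6527, no filter 6218, DESeq2 6481 and limma-voom 7282, against 6404.

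Lists called with an estimated correlation numbered 0 in each of the 5 contrasts, against 14, 19, 13, 5 and 11. Fry, which tests whether a list moves without setting it against other genes, called 25 at 5 wpi, 12 over time in idd7 and 0 for the interaction. Leaving out 1 library gave 4 to 8 lists over time in idd7 (8 without 5 wpi replicate 2 or 7 wpi replicate 1). KSL4 (Os04g0179700) reversed over time in idd7, from −2.70 (adjusted p = 0.0463, 0.00966 to 0.625 over the alternatives) to 0.40 (adjusted p = 0.544) without 5 wpi replicate 1, with −3.25 at the other end when 1 library was left out. That library alone among the idd7 ones at 5 wpi held most of the KSL4 counts.

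With replicate numbers as a block, 6283 genes passed at 5 wpi, 9990 at 7 wpi, 3227 and 8482 over time in Azygous and idd7, and 968 for the interaction. At 5 wpi same-numbered libraries correlated at −0.0636, −0.0685 and −0.0309, and only at 7 wpi did every library correlate best with its own number. A block in a fit of the 7 wpi libraries alone called 9866 genes (8993 without the block), 9154 of them also called over all libraries, and ended 1 of 19 list calls, common symbiosis signalling. Thinning gave 6176, 9744, 3256, 8077 and 1189 genes.

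Splits of the 6 libraries of a contrast are 10, too few for a share under 0.05. In each of the 4 contrasts 1 split, the real one, reached the real count (6404, 10151, 3329 and 8658), and the highest other split called 0 genes by edgeR. Every other split put libraries of both real groups on each side, so a real difference between the groups added to its spread. The 0 calls are therefore no measure of chance.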

Other observations

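The scan of shared descriptions and the list of described mycorrhiza genes were tests chosen only after the results were seen. In the scan, 218 families of at least 8 genes were tested by camera, and 14, 32, 27, 11 and 19 were called at 5 wpi, at 7 wpi, over time in Azygous, over time in idd7 and for the interaction, against 0 in each with an estimated correlation. At 7 wpi, among families picked from those called, 10 of 12 FAS1 domain genes were higher and 1 lower (median 1.43). Higher too were 13 of 17 plant disease resistance response (dirigent type) genes (1.21) and 6 of 8 purple acid phosphatases (1.37). Lower were 52 of 282 pentatricopeptide repeat genes (5 higher, −0.21) and 67 of 174 NB-ARC genes (23 higher, −0.27). For these families the adjusted p with an estimated correlation was 0.646 to 0.685.

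Over time, FAS1 genes fell in Azygous (10 of 12, median −1.02), and kinesins fell in Azygous (5 of 8, −1.06) and in idd7 (8 of 8, −0.98), with adjusted p of 0.556, 0.553 and 0.732 by the estimated correlation. DNA replication genes had 12 lower and 0 higher of 31 over time in Azygous (median −0.43, camera adjusted p = 0.0136, or 0.54 with an estimated correlation) and 11 lower and 2 higher in idd7 (−0.26, 0.0416, or 0.706). All 8 genes described as mycorrhiza-specific markers were lower in idd7 at 5 wpi (median −7.78, camera adjusted p = 2.38e-12, or 0.1 with an estimated correlation) and at 7 wpi (−5.42, 1.14e-08, or 0.244). Over time in idd7 3 of the 8 were higher (median 2.75 at the count bounds, 0.0217, or 0.64) and in Azygous 1 (0.0685, not called). In the interaction 2 were higher and the list was not called (camera adjusted p = 0.282).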
